A study of Sus scrofa with 6 samples.

How the data were processed

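Gene expression was measured in the longissimus dorsi, the long muscle of the back, of 6 boars aged 150 days. There were 3 Large White boars, the control breed, and 3 Northeastern Indigenous boars, kept under shared feeding and housing per the labels. Each animal gave 1 Affymetrix Porcine Genome Array, hybridized with biotin-labelled cRNA made from total RNA, per the labels' protocols. The labels call the samples biological replicates.

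The authors deposited 1 linear intensity per probe set and array, with no detection calls used here. The software and settings that made these values are not given in the sources used here. On each array the mean of the deposited intensities, without the lowest and highest 2%, lay between 499.774 and 499.837, so the arrays had been brought to a shared scale before deposit. Each array gives brightness rather than read depth, and the precision is limited by the number of arrays.

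The table held 24123 probe sets, of which 124 were Affymetrix controls and were left out of all comparisons. Names came from the platform annotation. Of the other 23999 probe sets, 10069 had 1 gene symbol, 198 had several and 13732 had none listed, and no gene was named from a probe set with several. Gene identifiers of 9961 probe sets were found in the RefSeq gene table of assembly Sscrofa11.1, which changed 0 symbols. No genome build is given in the sources used here, so no coordinates are printed.

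Intensities were all above 0 and were taken as log2. The medians of the 6 arrays spanned 0.35 on the log2 scale, above the limit of 0.2 set beforehand, so the arrays were quantile normalized. Probe sets at or above the 40th percentile of mean log2 intensity were kept, which left 14399 probe sets and 5438 named genes. A gene with several probe sets was represented by the one with the highest mean. Differences are Northeastern Indigenous minus Large White, fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with 4 residual degrees of freedom. The Benjamini-Hochberg adjusted p had to be under 0.05. Quoted errors are SDs over 3 arrays or the SE of limma's difference.

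Before the data were examined, 31 gene lists were fixed: 30 on muscle fibres, metabolism, growth, stress and other cell types, and 1 of sex-linked genes, which served only to check the labels. The 29 lists with at least 4 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. The neuromuscular junction list had 2 measured members, CHRNA1 and GADD45A, and was not tested. An estimated correlation and limma's fry were run as alternatives. Fry asks whether the genes of a list move 1 way on balance and does not compare the list with other genes.

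Genes are named by a rule fixed at the same time. In each direction it takes the 10 genes of largest difference among those past the threshold with no overlap between breeds. Where fewer pass, it fills up to 10 in order of unadjusted p, with values only, and skips symbols that are only a LOC or clone identifier. It adds 36 fixed candidate genes where measured, and up to 4 members of each list.

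The fit was tested on simulated data with the real means and spreads and 200 changed probe sets among 14399, in 10 runs. With the spread of both breeds, the Northeastern Indigenous minus Large White fit recovered 2.54% of probe sets changed 2-fold, 37.5% of those changed 4-fold and 67.0% of those changed 8-fold. With the smaller spread of the Northeastern Indigenous arrays it recovered 31.3%, 68.2% and 83.3%. The simulated probe sets varied independently, with the same spread in both breeds. On the real arrays the first principal component held 69.4% of the variance. The median SD was 0.49 in Large White and 0.27 in Northeastern Indigenous boars. The recovery rates therefore may not carry over to the real arrays.

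The alternatives were other scalings, filters, offsets, variance priors, thresholds, array weights, the replicate number as a block, the mean of all probe sets of a gene, and leaving out each array in turn. Leaving out Large White replicates 1 and 3 together, and a covariate made of the adipocyte list mean minus the sarcomere list mean, were chosen after seeing the data.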

Results

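The series compared back muscle of 3 Northeastern Indigenous boars with that of 3 Large White boars, the control breed, all aged 150 days. One array was read per animal. The median deposited intensity ran from 94.1 on Northeastern Indigenous replicate 1 to 120.1 on Large White replicate 1. EIF1AY, the single measured gene of the sex-linked list, had log2 intensities from 10.92 to 11.94 on the 6 arrays.

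Adipocyte genes were bright and muscle genes dim on part of the Large White arrays. ADIPOQ, which encodes the fat-cell hormone adiponectin, had log2 intensities of 13.64 on Large White replicate 1 and 12.50 on replicate 3, against 7.22 on replicate 2. In Northeastern Indigenous boars it was 7.38 ± 0.81 (SD, n = 3). PPARG, the regulator of fat-cell formation, read 11.88, 6.34 and 10.58 on Large White replicates 1, 2 and 3. The intermediate filament gene DES read 7.26, 13.23 and 11.59 on the same arrays, and 13.21 ± 0.38 (SD, n = 3) in Northeastern Indigenous boars. The adipocyte list of 10 genes lay at a median of 3.18 log2 units above the Northeastern Indigenous mean on Large White replicate 1, 0.12 on replicate 2 and 2.03 on replicate 3. The sarcomere and Z-disc list of 15 genes lay at -4.40, -0.01 and -0.89.

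Whole profiles followed the same order. Large White replicate 2 correlated with the Northeastern Indigenous arrays at r = 0.92 to 0.95 across probe sets, and with Large White replicate 1 at 0.75. The Northeastern Indigenous arrays correlated with each other at 0.94 to 0.96. Genes are not independent replicates in these correlations. The first principal component held 69.4% of the variance and did not part the breeds (exact permutation p = 0.2, two-sided, n = 3 per breed; 0.1 is the smallest p this design allows). The median SD per probe set was 0.49 in Large White and 0.27 in Northeastern Indigenous boars.

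**Figure D1:**
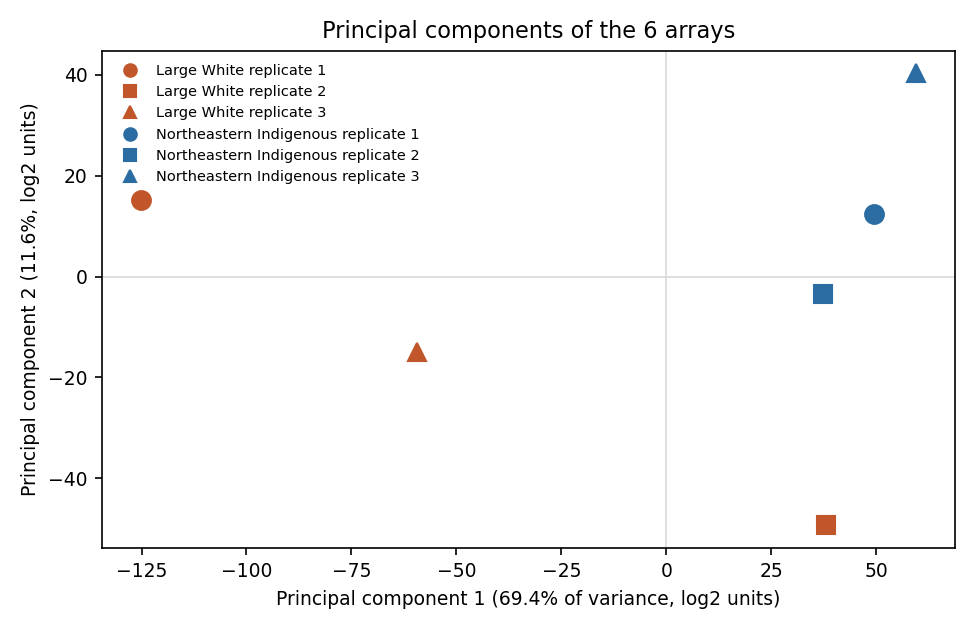
Each point is 1 array on the first (horizontal) and second (vertical) principal component of quantile-normalized log2 intensities, in log2 units, coloured by breed and shaped by replicate. Large White replicates 1 and 3 lie at -125.1 and -59.4 on the first component, and the other 4 arrays between 37.4 and 59.5.

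Between the breeds, the genes with the smallest unadjusted p included ISG12(A) and GBP1, dimmer in Northeastern Indigenous boars, and RETREG1 and NNT, brighter in them. ISG12(A), an interferon-induced gene, differed by -2.27 ± 0.25 log2 units (SE; 10.25 ± 0.26 against 12.53 ± 0.24, SD, n = 3 per breed). GBP1, an interferon-induced GTPase, differed by -3.60 ± 0.46, and RETREG1, a receptor for selective autophagy of the endoplasmic reticulum, by 2.02 ± 0.25 (SE). NNT, the mitochondrial proton-pumping transhydrogenase, differed by 1.37 ± 0.23 (SE). None of them passed the adjusted threshold.

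Limma called 0 of 14399 probe sets and 0 of 5438 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.057, at a locus without a gene name. At an unadjusted p under 0.05 there were 2706 probe sets, 1270 higher and 1436 lower in Northeastern Indigenous boars, where chance gives about 720. The breeds did not overlap in 28.3% of genes, against 10% by chance. Both chance values are averages, and genes moved together on these arrays, so any single split can lie far from them. Neither count was made for the other splits. Without Large White replicate 2 the calls came to 4421 probe sets and 1848 genes, and without Large White replicates 1 and 3 together to 0 of each. The 4421 and 1848 set Large White replicates 1 and 3 against the Northeastern Indigenous arrays. Those 2 arrays stood apart on the first component, so these counts cannot tell breed from whatever sets them apart. Array weights gave 8499 probe sets, with a weight of 42.0 on Large White replicate 3 and at most 1.36 on any other array.

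The 10 named genes higher in Northeastern Indigenous boars were RETREG1, CARD19, UBXN2A, NNT, HTATIP2, UGP2, ACADVL, CDC37L1, ZNF385D and CCNJ, with differences from 1.27 to 2.03 log2 units. UGP2, which makes UDP-glucose for glycogen, differed by 1.41 ± 0.27 (SE), and ACADVL, which starts the oxidation of very long fatty acids, by 1.70 ± 0.33. The 10 lower were ISG12(A), GBP1, KMO, OAS1, C1S, C1R, SLA-DMB, RND3, CASP1 and C4A, from -3.60 to -1.61. All 20 had adjusted p between 0.223 and 0.224 in limma. In all 20 the breeds did not overlap, which choosing the smallest p makes likely. Second probe sets of RETREG1 (1.82), UGP2 (1.88), ACADVL (1.58) and CDC37L1 (2.05) had differences of the same sign, as did the other probe sets of GBP1 (-3.10 and -0.65) and RND3 (-0.41).

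**Figure D2:**
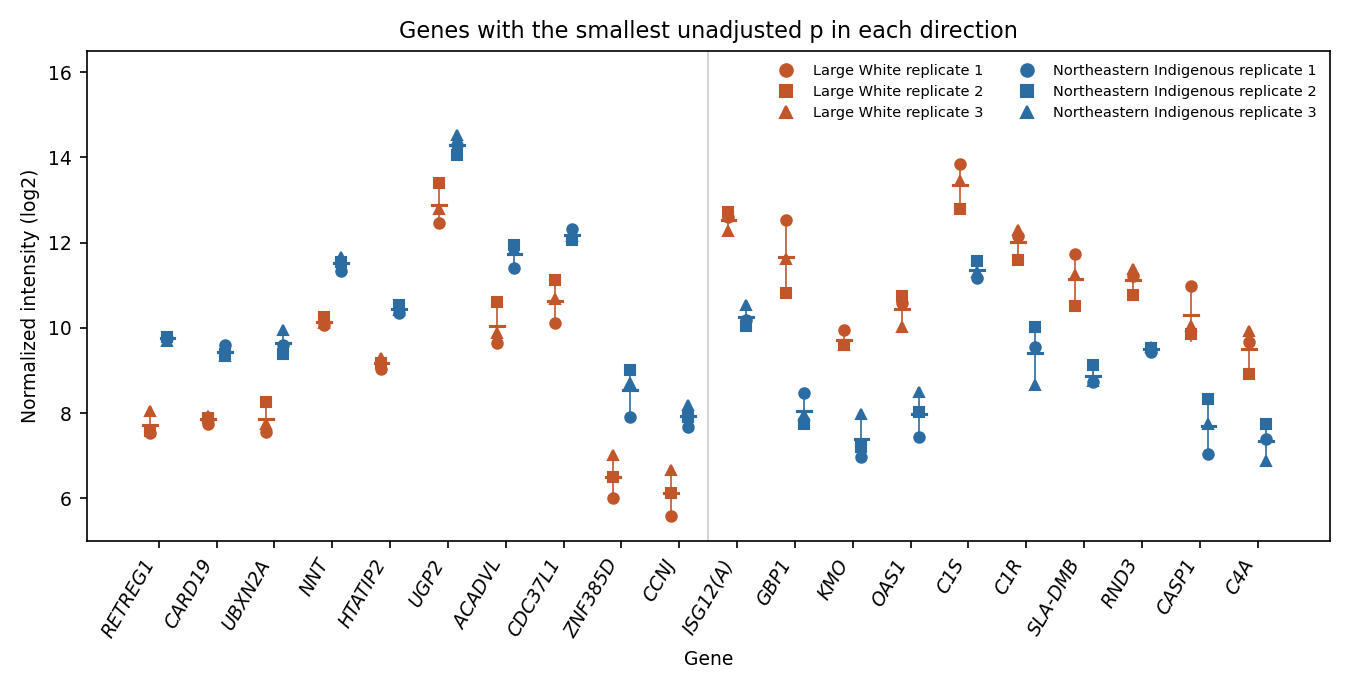
Normalized log2 intensity (vertical axis) of the 20 named genes of smallest unadjusted p (horizontal axis), 10 per direction, passing over symbols that are only a LOC or clone identifier, with points for arrays, horizontal lines for breed means and vertical lines for 1 SD (n = 3). The 3 arrays of each breed lie apart for each of the 20 genes, which choosing the smallest p makes likely, and none passed the adjusted threshold.

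Among 29 gene lists camera called 12, 5 higher and 7 lower in Northeastern Indigenous boars. With an estimated correlation it called 0, with 0 at an unadjusted p under 0.05, and fry called 0, with 7 at an unadjusted p under 0.05. The 9 other splits of the 6 arrays into 3 and 3, which mix the breeds, gave 5 to 13 called lists each. Many camera calls thus came from any grouping of these arrays, and splits this few cannot give a share under 0.05.

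Antigen presentation and interferon genes were dimmer in Northeastern Indigenous boars. The list of 33 measured genes had a median difference of -1.41 log2 units and was called lower by camera (adjusted p = 1.0e-14; adjusted p = 0.563 with an estimated correlation). OAS1, a sensor of viral RNA, differed by -2.46 ± 0.36 (SE), SLA-DMB, which loads peptides on class II molecules, by -2.28 ± 0.36, and TAP1, a peptide transporter for class I, by -1.60 ± 0.32. None of the 33 passed over all probe sets, and 23 passed adjusted over the list alone, all lower. Against Large White replicate 2 by itself the median was -0.95, with 32 of 33 genes lower. On that array the adipocyte list lay 0.12 above the Northeastern Indigenous mean and the leukocyte list 0.57 above it, with 18 of 21 leukocyte genes lower in Northeastern Indigenous boars. The leukocyte list on Northeastern Indigenous replicate 2 lay 1.08 above the other arrays of its breed, so the 0.57 is inside the spread of that breed.

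Leukocyte, matrix and cell-cycle genes were also dimmer in Northeastern Indigenous boars. The leukocyte list of 21 genes had a median of -1.79 (camera adjusted p = 4.8e-08; adjusted p = 0.563 with an estimated correlation), with C1QC, a complement gene of macrophages, at -3.30 ± 0.58 (SE) and AIF1, a macrophage marker, at -2.42 ± 0.55. The extracellular matrix and fibroblast list of 29 genes had a median of -1.34 (camera adjusted p = 3.5e-08; adjusted p = 0.563 with an estimated correlation), with SPARC at -1.34 ± 0.29 and POSTN at -3.96 ± 1.12. The cell-cycle list of 14 genes had a median of -0.58 (camera adjusted p = 0.005; adjusted p = 0.563 with an estimated correlation), with TOP2A, a topoisomerase of dividing cells, at -2.59 ± 0.59. Over all probe sets 0 members passed, and adjusted over the list alone 8, 0 and 1 passed. Without Large White replicates 1 and 3 the matrix and cell-cycle lists were no longer called (adjusted p = 0.193 and 0.201), and the cell-cycle list was not called under the 60th percentile filter (0.178) or with the adipocyte minus sarcomere score as covariate (0.060). The adipocyte list moved with these groups on those arrays, at 3.18 and 2.03.

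Genes of mitochondrial energy metabolism were brighter in Northeastern Indigenous boars. All 37 measured oxidative phosphorylation genes had a positive difference, with a median of 0.73 (camera adjusted p = 1.1e-09; adjusted p = 0.563 with an estimated correlation). ATP5G1, an ATP synthase subunit, differed by 1.43 ± 0.37 (SE) and NDUFS7, of complex I, by 1.34 ± 0.28. The tricarboxylic acid cycle list of 21 genes had a median of 0.74 (camera adjusted p = 5.8e-05; adjusted p = 0.563 with an estimated correlation), with MDH2 at 1.27 ± 0.30 and SDHA at 0.97 ± 0.24. The list for fatty acid uptake and oxidation, 23 genes, had a median of 0.52 (camera adjusted p = 0.016; adjusted p = 0.563 with an estimated correlation), with CPT1B, the muscle carnitine transferase, at 2.49 ± 0.61. Over all probe sets 0 members passed, and adjusted over the list alone 25, 8 and 1 passed. Against Large White replicate 2 by itself the medians were 0.36, 0.47 and 0.45, and that of the sarcomere list was 0.01. The slow-twitch list was at 0.21 there, with 10 of 11 genes higher in Northeastern Indigenous boars, and the fast-twitch list at -0.02. These 2 values depended on scaling. As deposited, Large White replicate 2 stood at -0.04 from the Northeastern Indigenous mean for slow-twitch and 0.25 for fast-twitch. For oxidative phosphorylation it stood at -0.33. The fatty acid oxidation list was not called without Large White replicate 2 (adjusted p = 0.087) or without Northeastern Indigenous replicate 3 (0.066).

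**Figure D3:**
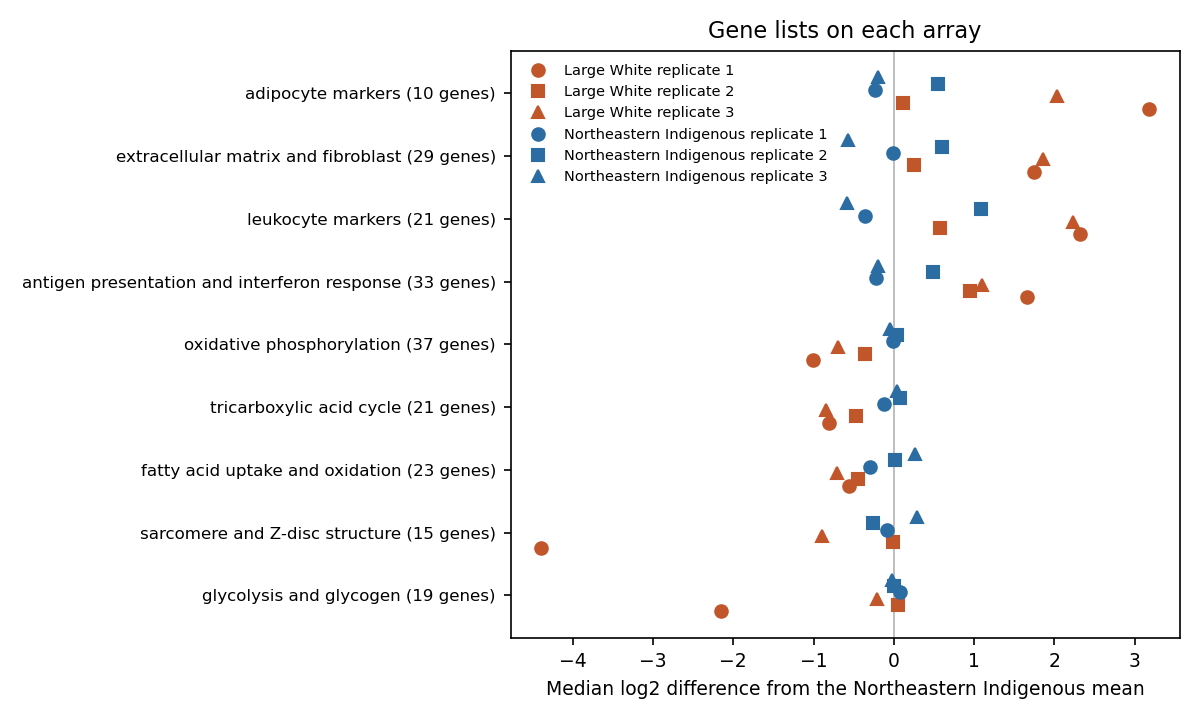
Median log2 difference of each of 9 gene lists (vertical axis) from the Northeastern Indigenous mean (horizontal axis), with 1 point per array; a Northeastern Indigenous array is set against the other arrays of its breed. Large White replicate 1 lies at 3.18 for adipocyte markers and -4.40 for the sarcomere list, and Large White replicate 2 at 0.95 for antigen presentation and -0.36 for oxidative phosphorylation.

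Adipocyte and cholesterol genes were dimmer in Northeastern Indigenous boars. The adipocyte list had a median of -1.76 (camera adjusted p = 0.005; adjusted p = 0.563 with an estimated correlation), and FABP4, the fat-cell fatty acid carrier, differed by -1.66 ± 0.70 (SE) with an SD of 1.54 in Large White and 0.35 in Northeastern Indigenous boars (n = 3 per breed). The cholesterol list of 10 genes had a median of -1.02 (camera adjusted p = 0.040; adjusted p = 0.563 with an estimated correlation), with INSIG1 at -2.08 ± 0.59 (SE) and MSMO1 at -2.15 ± 0.53. The fatty acid and triglyceride synthesis list of 15 genes had a median of -0.29, with 5 genes higher and 10 lower, and did not pass (camera adjusted p = 0.0715). Within it were SCD, the desaturase that makes oleate, at -3.91 ± 1.00, FASN, the fatty acid synthase, at -3.82 ± 1.08 and PNPLA3 at -4.06 ± 0.88. Against Large White replicate 2 by itself these differences were smaller, at -1.92, -1.29 and -2.01. PNPLA3 was dim in Northeastern Indigenous boars, at 4.15 ± 0.67 (SD, n = 3), under the deposited array medians of 6.56 to 6.91. The lipolysis list of 8 genes had a median of -0.50 (camera adjusted p = 0.196). Over all probe sets 0 members passed, and adjusted over the list alone 0 adipocyte, 2 cholesterol, 3 fatty acid synthesis and 0 lipolysis genes passed. Without Large White replicates 1 and 3 the adipocyte and cholesterol lists had medians of -0.12 and -0.38. With the covariate neither list was called (camera adjusted p = 0.201 and 0.297). The covariate is built in part from the adipocyte list, so the loss of that list's call could follow from its construction. Without Large White replicate 1 the medians were -1.04 and -0.50, with -0.17 for fatty acid synthesis and -0.22 for lipolysis, and the cholesterol list was not called there (0.079) or without Northeastern Indigenous replicate 1 (0.064) or 3 (0.054), or under the 60th percentile filter (0.066). The fatty acid synthesis list was called lower without Large White replicate 3 (0.043) or Northeastern Indigenous replicate 2 (0.049), and under the 60th percentile filter (0.048).

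Muscle structure and glycolysis genes were brighter in Northeastern Indigenous boars, with most of the difference on Large White replicate 1. The sarcomere list of 15 genes had a median of 1.77 (camera adjusted p = 0.0055; adjusted p = 0.777 with an estimated correlation), with ACTN2, which anchors actin at the Z-disc, at 13.82 ± 0.23 against 11.47 ± 2.78 (SD, n = 3 per breed). The glycolysis and glycogen list of 19 genes had a median of 0.91 (camera adjusted p = 0.036; adjusted p = 0.777 with an estimated correlation). Adjusted over the list alone 0 and 1 members passed, and 0 over all probe sets. Without Large White replicates 1 and 3 the medians were 0.01 and -0.06. With the covariate, which is built in part from the sarcomere list, they were -0.43 and -0.26. Without Large White replicate 1 the sarcomere median was 0.39, the glycolysis median 0.08 and the difference of ACTN2 0.77. The glycolysis list was not called without Large White replicate 1 (adjusted p = 0.397), Northeastern Indigenous replicate 1 (0.064) or 3 (0.053). Fast-twitch (0.66), slow-twitch (1.32), calcium-handling (0.68) and myogenic (0.85) lists had positive medians and did not pass (camera adjusted p = 0.106, 0.242, 0.286 and 0.359), though the fast-twitch and slow-twitch lists were called higher without Large White replicate 3 (0.014 and 0.027). Without Large White replicate 1 these medians were 0.02, 0.28, 0.009 and 0.12.

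Ribosomal protein genes differed little. The list of 50 genes had a median of -0.10 and was called lower by camera (adjusted p = 0.030; adjusted p = 0.563 with an estimated correlation), but it was called higher without quantile normalization (median 0.22, adjusted p = 0.030) and with arrays centred on their medians (median 0.36, adjusted p = 0.021). RPS4X, a small-subunit protein, differed by -0.73 ± 0.20 (SE). The list was not called without Large White replicate 2 (adjusted p = 0.077), Northeastern Indigenous replicate 2 (0.058) or 3 (0.054), without Large White replicates 1 and 3 together (0.193) or with the covariate (0.121). Adjusted over the list alone and over all probe sets, 0 ribosomal genes passed.

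The other lists did not pass camera. Their medians were -0.41 for antioxidant genes, -0.24 for proteolysis, 0.39 for smooth muscle, 0.28 for heat shock, -0.31 for blood cells, 0.28 for the circadian clock, 0.18 for endothelium, -0.11 for IGF and insulin signalling, 0.16 for nerve, 0.10 for hypoxia and glucocorticoid response and -0.07 for immediate early genes. The mean of the immediate early list was 0.14, opposite in sign to its median. The antioxidant list was called lower without Large White replicate 3 (adjusted p = 0.027), Northeastern Indigenous replicate 2 (0.049) or 3 (0.044), and without Large White replicate 1 its median was -0.22 (0.367). Leaving out 1 array gave medians from -0.04 to 0.37 for heat shock, 0.04 to 0.54 for the clock, 0.05 to 0.34 for endothelium, 0.05 to 0.17 for hypoxia and -1.19 to 0.18 for blood cells. For smooth muscle the range was 0.25 to 0.52. Within these lists FBXO32, a muscle ubiquitin ligase, differed by 2.64 ± 0.77 (SE), FKBP5, a glucocorticoid-induced chaperone, by 1.88 ± 0.51, HSPB7 by 2.45 ± 0.54 and CAPN2 by -0.77 ± 0.24, with adjusted p of at least 0.224 in limma.

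Of the 36 candidate genes fixed beforehand, 29 were measured and 0 passed. MSTN, which limits muscle growth, differed by 1.43 ± 1.45 (SE), MYOD1, the myogenic factor, by 1.19 ± 1.14, IGF2 by 0.46 ± 0.42, PRKAG3 by -0.35 ± 0.78, CAST by -0.44 ± 0.29 and CAPN1 by -0.10 ± 0.40. FABP3, the muscle fatty acid carrier, differed by 0.12 ± 0.41, PPARGC1A by 2.71 ± 1.09 and PDK4 by 1.43 ± 1.15. Leaving out 1 array gave differences from -0.41 to 2.63 for MSTN, -0.12 to 2.45 for MYOD1, 0.16 to 0.93 for IGF2, -1.10 to 0.45 for PRKAG3, -0.37 to 0.20 for CAPN1 and -0.36 to 0.51 for FABP3. PDK4 was at 0.14 without Northeastern Indigenous replicate 3, PPARGC1A at 1.40 without Large White replicate 1 and CAST at -0.23 without Northeastern Indigenous replicate 2. The fibre genes MYH7 (1.95 ± 1.19), MYH2 (0.60 ± 0.50), TNNT1 (2.13 ± 1.28) and RYR1 (2.13 ± 1.41) all had SDs above 1 in Large White and below 0.5 in Northeastern Indigenous boars, and without Large White replicate 1 they were at 0.39, -0.04, 0.45 and 0.34.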

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

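Alternatives were chosen before the data were examined, except leaving out Large White replicates 1 and 3 together and the adipocyte minus sarcomere covariate, chosen after seeing the data. The count of 0 probe sets and 0 genes held without quantile normalization, under both filters, the offset, both variance priors, a 2-fold requirement and the replicate block (0 and 0). It became 1 and 1 with median centring, with the covariate and at an adjusted p under 0.1, 1 gene with the mean of all probe sets, and 563 probe sets and 243 genes at an unadjusted p under 0.01 and 2-fold. Array weights, whose estimation did not converge and put 42.0 on Large White replicate 3, gave 8499 and 3289. Leaving out 1 array gave 0 to 4421 probe sets and 0 to 1848 genes, the highest without Large White replicate 2. The Large White arrays then left are replicates 1 and 3, which stood apart from the other arrays on the first principal component. These highest counts therefore cannot tell breed from whatever sets those 2 arrays apart. The 12 called lists became 0 with an estimated correlation, 0 with fry, 5 without Large White replicates 1 and 3 (1 array is then assumed to vary like the others), where an estimated correlation gave 0, 6 with the covariate, 11 with the replicate block (ribosomal 0.066), and 9 to 16 without 1 array. Array weights left 9, without the sarcomere (adjusted p = 0.154), cholesterol (0.119) and glycolysis (0.368) lists. The 60th percentile filter kept 12, losing cell cycle (0.178) and cholesterol (0.066) and adding fatty acid synthesis (0.048) and antioxidant (0.020). Fast-twitch was called as deposited (0.020) and with median centring (0.040), and fatty acid synthesis with the mean of all probe sets (0.046). Same-numbered arrays did not deviate together (r = -0.02, -0.16 and -0.11), so the numbers were not read as pairs. Scaling moved the median of all probe sets from 0.10 with quantile normalization to -0.003 as deposited and 0.14 with median centring. Agreement of probe sets at an unadjusted p under 0.01 and 2-fold was 77.4% with no filter; at the adjusted threshold 0 probe sets gave no agreement value. Signs turned as follows, and the cause was not tested. Without Large White replicates 1 and 3: fast-twitch -0.0174, calcium handling -0.0352, lipolysis 0.0905, glycolysis -0.0556, myogenic -0.15, heat shock -0.0527, circadian -0.57, antioxidant 0.00515, blood 0.17, nerve -0.16, FABP4 0.12, LPL 1.01, ADIPOQ 0.16, PLIN2 0.35, MYH2 -0.0174, MSTN -0.98, MYOD1 -1.35, IGF1 0.31, IGF2 -0.46, RYR1 -0.47, PYGM -0.10, ATP2A1 -0.20, HRC -0.23, CAMK2G -0.18, LIPE 0.88, ATF3 -0.23, RORA -0.27, DBP -0.21, PER1 -0.57, ACTG2 0.0879 and ALAS2 0.23. With the covariate, which is built from the adipocyte and sarcomere lists: sarcomere -0.43, glycolysis -0.26, slow-twitch -0.38, fast-twitch -0.36, calcium handling -0.35, myogenic -0.20, heat shock -0.13, circadian -0.41, nerve -0.14, lipolysis 0.00148 and immediate early 0.11. As deposited: ribosomal 0.22, hypoxia -0.0219, nerve -0.39, RPL31 0.0612, RPSA 0.0157 and HBB -0.0696. With median centring: ribosomal 0.36, immediate early 0.0478, nerve -0.25, RPL31 0.20 and RPSA 0.16. With array weights: IGF and insulin 0.11, FABP3 -0.0688, MYH2 -0.0470, CAPN1 0.22 and HBB -0.0740. With log2(value + 16): nerve -0.19. Leaving out 1 array, ranges crossing 0 were IGF and insulin -0.15 to 0.17, heat shock -0.0357 to 0.37, immediate early -0.18 to 0.13, blood -1.19 to 0.18, nerve -0.0292 to 0.50, FABP3 -0.36 to 0.51, MYH2 -0.0423 to 0.94, MSTN -0.41 to 2.63, MYOD1 -0.12 to 2.45, PRKAG3 -1.10 to 0.45, CAPN1 -0.37 to 0.20, BHLHE40 -0.000963 to 1.09, ALAS2 -1.37 to 0.18, HBM -1.19 to 0.33 and HBB -0.12 to 0.18.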

Other observations

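The gene families and tests in this part were chosen after the results were seen, except the agreement of probe sets and the splits of the arrays for probe sets, which were written down before. The agreement was written down for called probe sets, and its threshold was changed to an unadjusted p after 0 were called. Mitochondrial ribosomal proteins were brighter in Northeastern Indigenous boars, with a median difference of 0.66 log2 units over 58 genes, 55 of them positive (camera adjusted p = 2.1e-09 over 18 families, of which 7 were called; adjusted p = 0.545 with an estimated correlation). Against Large White replicate 2 by itself the median was 0.20, while the sarcomere list lay at -4.40 and -0.89 on Large White replicates 1 and 3. MRPL35 differed by 0.83 ± 0.21 (SE) and MRPS36 by 1.07 ± 0.30. All 18 measured TIMM and TOMM genes of mitochondrial import were positive (median 0.74, and 0.16 against Large White replicate 2 by itself; camera adjusted p = 0.00031; adjusted p = 0.552 with an estimated correlation). The 33 proteasome subunits had a median of 0.32, and 0.19 against Large White replicate 2 (camera adjusted p = 0.0059; adjusted p = 0.545 with an estimated correlation), with PSMD12 at 1.05 ± 0.24, whereas PSMB8, a subunit of the interferon-induced immunoproteasome, was at -1.41 ± 0.43. The size of the proteasome median depended on scaling, at 0.48 as deposited and 0.62 with median centring.

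Complement components were dimmer in Northeastern Indigenous boars, with a median of -2.00 over 9 genes and 0 positive (camera adjusted p = 2.3e-06; adjusted p = 0.545 with an estimated correlation). C1R differed by -2.61 ± 0.41 (SE) and C1S by -2.00 ± 0.30, and the median against Large White replicate 2 by itself was -1.44. The 28 chemokines and interleukins had a median of -0.65, and -0.41 against Large White replicate 2, with 26 negative and CCL19 at -3.17 ± 0.65 and CXCL9 at -2.92 ± 0.83 (camera adjusted p = 1.6e-05; adjusted p = 0.545 with an estimated correlation). The 13 S100 proteins and annexins, which bind calcium, had a median of -1.18, and -0.29 against Large White replicate 2 (camera adjusted p = 0.0039; adjusted p = 0.589 with an estimated correlation). Of these 13 genes, 5 had all Northeastern Indigenous arrays above Large White replicate 2 and 2 had all below it. The 10 aldehyde dehydrogenases had -1.12 and -0.41 (camera adjusted p = 0.0067; adjusted p = 0.545 with an estimated correlation). The breeds did not overlap in 6 complement, 10 chemokine and interleukin, 2 S100 and annexin and 4 aldehyde dehydrogenase genes. On Large White replicates 1 and 3 the adipocyte (3.18 and 2.03), leukocyte (2.31 and 2.23) and matrix lists (1.74 and 1.86) were high as well, as was ANXA2, an annexin, at 14.91 and 14.47 against 11.91 on replicate 2.

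Large White replicates 1 and 3 stood apart from the other 4 arrays. RNA degradation would raise the 3' over 5' ratio of control genes, but the GAPDH ratios of these arrays reached 1.31 at most, below the 1.39 of Northeastern Indigenous replicate 2. EEF1A ratios were 0.97 and 1.06 on Large White replicates 1 and 3, against 1.24 to 1.43 on the other 4 arrays. ACTB ratios were 5.85 and 5.56, against 6.69 to 10.85. Both were lowest on replicates 1 and 3, the opposite of what degradation there would give, though they were not level over the arrays. Quantile normalization was argued against too, since the adipocyte list was at least 1.92 above the Northeastern Indigenous mean on both arrays in the values as deposited. The scaling done before deposit could not be checked in this way. Adipose tissue in the sample was weighed by a criterion set per array after these medians were seen. It asked for a raised adipocyte list that led the other non-muscle cell lists, and for a lowered sarcomere list. Replicate 1 met it and replicate 3 did not. The adipocyte list less the leukocyte list was 0.87 on replicate 1 (3.18 and 2.31, with a 95% bootstrap interval of -1.34 to 3.86). On replicate 3 it was -0.20 (2.03 and 2.23, interval -1.35 to 2.84). Both intervals hold values of either sign, so they do not decide which of the 2 lists led. They do not bear on whether the adipocyte list was raised. It stood at 3.18 and 2.03, against at most 0.55 on a Northeastern Indigenous array. The sarcomere list stood at -4.40 and -0.89, against -0.26 or higher on the Northeastern Indigenous arrays. Adipocyte transcripts were thus raised on both arrays, while adipose tissue in the sample as their source stays open. The hybridization spikes also parted these arrays, at median log2 values of 11.40 and 11.55 against 11.99 to 12.27 on the other 4, and so did the 28S rRNA control, at 1118 and 2650 against 4013 to 6238, so a difference in processing stays open, as does a difference between the animals, and neither was tested.

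The lower antigen presentation and interferon list may or may not come from the composition of Large White replicates 1 and 3. Without them the median was -0.95, beyond the 0.47 that parted Northeastern Indigenous arrays at most, but this rests on 1 Large White array and so excludes nothing. A breed variant under single probe sets also stays open, with other probe sets going the same way in 83.3% of 6 genes (exact 95% interval 35.9 to 99.6%). A larger share of immune cells was not tested and stays open, as does a breed difference. The leukocyte list was 0.57 higher on Large White replicate 2 than the Northeastern Indigenous mean. Northeastern Indigenous replicate 2 lay 1.08 above the other arrays of its own breed, so this gap is inside their spread.

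The higher oxidative phosphorylation list is open in the same way. Without Large White replicates 1 and 3 the median was 0.36, against at most 0.046 between Northeastern Indigenous arrays, again from 1 Large White array. Other probe sets went the same way in 66.7% of 6 genes, too few to weigh a variant under single probe sets. A breed difference is among the open explanations.

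The hypothesis that Large White replicate 3 may hold the tissues of replicates 1 and 2 in 1 proportion was tested on the deposited intensities of genes at least 4-fold apart between those 2 arrays. The median share of replicate 1 was 0.50 for 8 adipocyte genes (95% bootstrap interval 0.34 to 0.62), 0.57 for 9 matrix genes, 0.58 for 14 sarcomere genes and 0.58 for 12 glycolysis genes. The matrix and adipocyte shares differed by 0.070, inside the 0.2 set for this test, and the intervals overlap widely. Over all 29 matrix genes, though, the medians above the Northeastern Indigenous mean were 1.74, 0.25 and 1.86 on replicates 1, 2 and 3, so replicate 3 did not lie between the other 2 there, and the hypothesis stays open.

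Of 95 genes with a probe set at an unadjusted p under 0.01 and 2-fold, and another probe set, 86.3% had all other probe sets going the same way (exact 95% interval 77.7 to 92.5%), above the 80% set against single-probe variants. It was 87.8% with the 60th percentile filter (75.2 to 95.4%) and 77.4% with no filter (70.3 to 83.6%), short of 80% but above the 60% set for such variants. Pairs of probe sets of other genes went the same way in 78.3%, 83.0% and 69.0%. The 78.3% and 83.0% lie inside the intervals of the chosen genes, and the 69.0% lies just under the 70.3% limit. The chosen genes thus agreed little more than others did, so these values do not decide on single-probe variants, in general or for single genes. FAM26F, chosen after its values were seen, had differences of -3.12 and 0.07 on its probe sets.

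The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 0 probe sets, 0 genes and 12 lists, and the highest of the other splits gave 0, 0 and 13. With 0 calls on the real split, every split gives at least as many probe sets and genes, so that 10 of 10 did carries no information. As many lists came from 4 of 10 splits. Among the 124 control probe sets, 7 had all Northeastern Indigenous arrays above all Large White arrays and 3 had all below, where chance gives 6.2 each way.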
